A study of Oryza sativa with 6 samples.

How the data were processed

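Total RNA of flag leaves of 3 wild type and 3 mutant samples was labelled with biotin and hybridised to Affymetrix Rice Genome Arrays, 1 array per sample. The authors' deposited values are log2 RMA values per probe set, made with the affy package per the submitters' processing notes, with versions not given in the sources used here. RMA corrects the background, equalises the distribution of probe intensities between arrays and summarises the probes of a set, so differences in total RNA between samples are removed. The deposited table held 57381 probe sets, among them 123 AFFX controls, which were left out of all tests. The scale was taken from the values, which lay between 1.65 and 14.5. The scanner files were not used here, so background, probe-level effects and scan batches were not analysed here.

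Probe sets were named through the platform annotation, and its Entrez identifiers were looked up in the RefSeq gene table of assembly ASM3414082v1. Of the 57258 probe sets tested, 22436 had 1 gene, 95 had several and 34727 had none in this annotation. All 17905 genes matched the RefSeq table, where 2457 had a name beyond a LOC or clone identifier. No coordinates were used, since the build behind the array was not given. A gene was represented by its single-gene probe set with the highest mean over all 6 arrays. Of 3444 genes with more than 1 probe set, 227 had 2 or more called ones, and 5 had called probe sets in both directions. Old names and shared probes limit the assignment, in particular for the 3159 single-gene probe sets ending in _x_at or _s_at, which can bind related transcripts.

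Mutant and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided, Benjamini-Hochberg adjusted p, threshold 0.05), without a block or covariate. Where single values are concerned, an exact permutation test of 3 against 3 arrays cannot go below p = 0.1. Fold changes are differences of mean log2 values, mutant minus wild type. Gene lists were tested with camera (preset correlation 0.01, lists of 5 or more measured members), with an estimated correlation and fry beside it. None of 25 lists passed with an estimated correlation. The fry test asks whether a list's genes move one way and does not compare them with other genes. It called 14, of which 11 were higher and 3 lower. As the median change of all genes was 0.10, fry calls of higher lists include that shift. The gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the targeted gene, the 12 largest rises and 12 largest falls among called genes with separated groups and a product name, and up to 4 members with the smallest adjusted p of each list.

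Parts of this plan had to be adapted. The lists named 202 rice loci and patterns for product names. The tables held none of these loci and no product names, so the lists were rewritten as gene symbols after the reference names were read and before any difference was computed. Likewise a name beyond a LOC or clone identifier stood for a product name, which left 757 eligible genes. The 26 rewritten lists had 1 with fewer than 5 members, which leaves 25, and 9 lists were added then. Members of a list are genes matched by name, so other genes of a family may be measured without being in its list. Lists of chloroplast ribosomal proteins, anion channels and guard cell markers had no matching names and were not analysed here. The choice of the 25 fixed lists as the main family, with all 34 beside it, was made after the results of the 35 lists had been seen, and both sets of adjusted p are given where they differ in call.

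The procedure was tested on simulated arrays for the comparison of mutant with wild type over 17905 genes, with 200 genes changed and a list of 20 others raised by 0.5. All 66 genes changed by 2 on the log2 scale were recovered, with 68.7% of those changed by 1 and 44.8% of those changed by 0.5, and 6 of all 156 calls, or 3.85%, were of unchanged genes, while 8 calls fell on the raised list. The simulated noise was independent between genes, with no offset between arrays and no outlying array, and fewer genes were changed than were called in the data. These shares therefore need not hold for the real arrays. Alternatives were a replicate block, other scalings, other variance models, array weights, each array left out in turn, a filter on dim probe sets, other gene summaries, stricter thresholds and a Welch test. Figures were drawn with matplotlib 3.10.9, and tables were joined with pandas 2.3.3 in Python 3.11.15.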

Results

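Transcript levels were measured in flag leaves of rice (Oryza sativa), the leaf just under the panicle, on the Affymetrix Rice Genome Array. Of the 6 arrays, 3 came from plants of the japonica cultivar Zhonghua11 and 3 from a line of this cultivar in which T-DNA, the DNA that Agrobacterium transfers, is inserted in OsSLAC7 (Os01g0385400). The labels call the arrays of each group biological replicates, without saying whether each came from a separate plant, so p-values measure the spread between these samples. Array medians lay between 4.58 for mutant replicate 1 and 4.72 for wild type replicate 3 on the log2 scale. Within groups, Pearson correlations across probe sets ranged from 0.992 (mutant replicates 1 and 2) to 0.996, and no array was a copy of another. The plants were untreated and were moved from a greenhouse to the field. The number of arrays limits the precision of all values.

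The series title names leaf damage in the mutant and protection against it as the subject. The comparison asks which transcripts differ between leaves with the disrupted gene and wild type leaves. The chitinases Cht4 and Cht5, enzymes that cut the chitin of fungal walls, rose by 5.84 (SE 0.15) and 2.90 (SE 0.08) on the log2 scale, with limma adjusted p = 1.75e-06 and 2.00e-06. Cht4 went from a level of 3.13 ± 0.19 in wild type to 8.97 ± 0.25 in mutant leaves (SD, n = 3 each). The dehydrins RAB21 and RAB16B, which accumulate in drying tissue, rose by 2.89 and 2.21, and LEA19, of the late embryogenesis abundant proteins, by 2.46. The expansins OsEXPB3 and OsEXPA2, which loosen cell walls, rose by 2.77 and 2.31. The nicotianamine synthase OsNAS3 fell by 1.39 (adjusted p = 0.000181), and OsKSL10, a diterpene synthase, fell by 1.32 (adjusted p = 0.00144).

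The other 5 of the 12 largest rises among genes with a name were GLT2 (2.79), MS (2.67), the homeobox gene HOX12 (2.23), BURP17 (2.17) and IAA20 LOC4340245 (2.06), which encodes a repressor of auxin response. The other 10 of the 12 largest falls ran from MADS34 (-1.26) and pla2-II (-1.22) to OsVIT1.2 (-0.86), a vacuolar iron transporter. Between them lay the glutaredoxin GRXC15 (-1.06), peroxidase LOC4344277 (-0.99), the glutathione S-transferase GSTF1 (-0.99), the oxophytodienoate reductase OPDAR1 (-0.98), OsPHO1;3 (-0.96), DI1 (-0.91) and the florigen gene Hd3a (-0.88). In each of these 24 genes the 3 mutant values lay on one side of the 3 wild type values, as the rule required. Chance alone separates 10% of genes in this way, and 45.6% of all genes were separated.

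**Figure D1:**
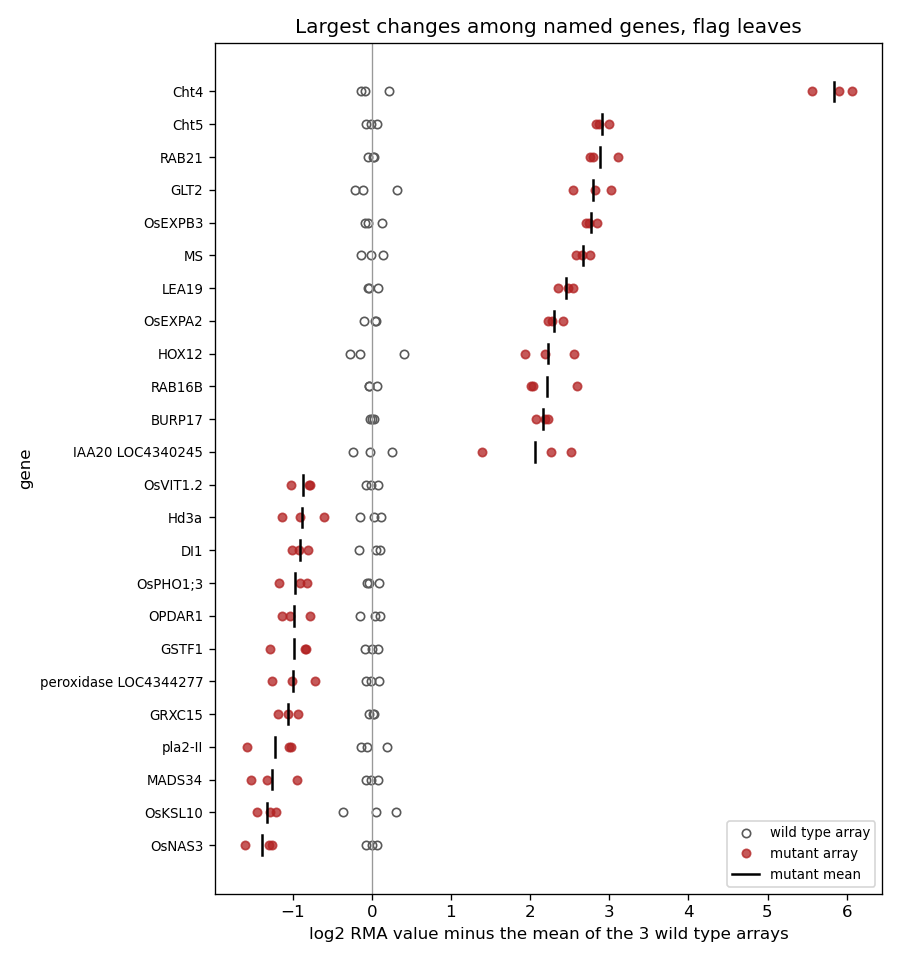
Log2 RMA value of each array minus the mean of the 3 wild type arrays (x axis, log2 units) for the 24 named genes with the largest changes (y axis). Open points are wild type arrays, filled points mutant arrays and bars mutant means. Cht4 lies farthest right, at 5.84, and OsNAS3 farthest left, at -1.39.

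Over all genes, 4883 of 17905, or 27.3%, passed the threshold, of which 3752 rose and 1131 fell. Of those past it, 593 (540 up, 53 down) changed by 1 or more on the log2 scale. Counts of list members given below stand against these shares, and more rises than falls are the rule over all genes too. Over all 57258 probe sets, 3735 rose and 1897 fell. The median of all genes was 0.10 higher in mutant leaves, and centring each array on the median of its genes, an alternative chosen after seeing the data, moved this median by -0.21, to -0.12. With that centring, which leaves most genes below 0, 1804 genes rose and 3935 fell. With each array shifted by the median deviation of its genes, also chosen after seeing the data, the median was -0.00 and 2704 rose and 2167 fell. Both move all genes of an array alike, so that falls gain on rises by construction. With each array centred on its median over probe sets, 4572 probe sets rose and 1358 fell, and 3995 genes rose and 641 fell. Without wild type replicate 2 there were 3000 genes past the threshold and without wild type replicate 3 there were 2700. The corresponding probe set counts were 2560 and 2319, and without wild type replicate 1 the probe set count was 3143. Mutant replicate 1 stood apart from the other mutant arrays, with an array weight of 0.441, and without it 2628 genes rose and 1024 fell.

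Genes of dehydration and abscisic acid response rose in mutant leaves. Of 28 measured members, 16 rose, none fell and 12 did not pass; adjusted over the list alone, 16 rose and 1 fell. After LEA19, RAB21 and RAB16B, Osem (1.40) and salT (1.49) rose most, and the protein phosphatases OsPP2C68 (0.90) and OsPP2C06 (0.73), which act in abscisic acid signalling, rose with them. DREB1A was -0.22 and DREB1C -0.45, neither past the threshold. The list median was 0.45, or 0.35 above that of all genes. This was the only one of 25 fixed lists past the threshold of the camera test (adjusted p = 0.0486), and with an estimated correlation the call was lost (adjusted p = 0.717). It was also lost without wild type replicate 1 (adjusted p = 0.0507) and without mutant replicate 2 (0.104). The same held with a replicate block (0.0648), with array weights (0.0551) and without probe sets ending in _x_at or _s_at (0.0579). Over the 16 alternatives with the preset correlation the camera adjusted p ran from 0.00109 to 0.104. After centring on the median of the genes 12 members rose and 3 fell. By fry the list was higher (adjusted p = 0.00307).

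Markers of panicle and flower organs stood higher in the same mutant arrays, with 11 of 19 members past the threshold upward and none downward, the same counts as adjusted over the list alone. MADS7 rose by 1.71, OsMADS24 by 1.57, OsMADS5 by 1.40 and OsC4 by 1.30. MADS34, a MADS-box gene outside the list, fell, as given above. The list as a whole had an adjusted p of 0.0503 among the 25 fixed lists, or 0.717 with an estimated correlation. Among all 34 lists it passed (adjusted p = 0.0342), and with an estimated correlation it did not (adjusted p = 0.710). Without mutant replicate 1 it had 9 rising members and an adjusted p of 0.0212, and it also passed without wild type replicate 2 (0.0399), wild type replicate 3 (0.0143) or mutant replicate 3 (0.0257). It did not pass without wild type replicate 1 (adjusted p = 0.0507) or mutant replicate 2 (adjusted p = 0.120). Nor did it pass with a replicate block (0.0648), with array weights (0.0745) or without probe sets ending in _x_at or _s_at (0.0579). Over the 16 alternatives with the preset correlation its camera adjusted p ran from 0.00158 to 0.120. With arrays centred on the median of the genes 9 members rose and 2 fell, and the median of the dividing-cell markers turned from 0.21 to -0.00. Of 26 dividing-cell markers, 8 rose, among them the mitotic cyclins CycB2;2 (1.37) and CycB1;1 (1.34), with an adjusted p of 0.329 for the list, and 4 rose without mutant replicate 1, mutant replicate 2 or wild type replicate 1 and 5 without wild type replicate 3. The median of their mean levels over all 6 arrays was 4.37, below the median of each array. Of 14 epidermis and wax markers 6 rose, led by the lipid transfer protein gene LTP110-A (1.61), and adjusted over the list alone 6 rose and 1 fell, with an adjusted p of 0.376; 3 rose without wild type replicate 1 or wild type replicate 3. Of 15 vascular and secondary wall markers 3 rose, led by the laccase LAC7 (1.97), with an adjusted p of 0.953. By fry the panicle (adjusted p = 0.0109), dividing-cell (0.0302) and vascular markers (0.0182) were higher.

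Expansins and auxin response genes were covered by lists added once the reference names were known and before any difference was computed. In one family of 34 lists, expansins passed with 14 of 29 members up and 2 down (adjusted p = 0.0330), a call lost with an estimated correlation (adjusted p = 0.714). OsEXPB4 (2.05) and OsEXPB6 (1.99) followed the pair named above. Auxin response genes passed with 23 of 52 members up and none down (adjusted p = 0.0405), a call also lost with an estimated correlation (adjusted p = 0.714). Adjusted over the list alone 28 rose, and with arrays centred on the median of the genes 12 rose and 6 fell. IAA30 rose by 1.66, IAA18 by 1.18 and IAA15 by 0.93. The panicle and flower organ markers, which belong to tissue other than leaf blade, moved with both. Without mutant replicate 2 the adjusted p was 0.0817 for expansins and 0.0694 for auxin response, and without wild type replicate 1 that of auxin response was 0.0671. Without wild type replicate 3 the rising auxin response genes numbered 14. By fry, over all 34 lists, expansins (unadjusted p = 0.000469) and auxin response (0.00147) passed the adjusted threshold upward. Over the 16 alternatives with the preset correlation the camera adjusted p ran from 0.000666 to 0.0817 for expansins and from 0.0235 to 0.0694 for auxin response.

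By camera none of the photosynthesis and pigment lists tested passed. By fry, which does not compare a list with other genes, the photosystem subunits (adjusted p = 0.0302) and carotenoid genes (0.0138) were lower, and the chlorophyll synthesis (0.0299) and breakdown genes (0.0182) higher. The median change of the chlorophyll synthesis list lay only 0.01 above that of all genes, and that of the breakdown list 0.12 above. The 3 light-harvesting antenna genes matched by name, too few to test as a list, differed by 0.12 (CAB2R), 0.02 (LHCP) and -0.09 (RCABP69). None of them passed or had an unadjusted p under 0.05 by limma. Of 11 photosystem and electron transport subunits, PSB28 (-0.56) and NDH-M (-0.47) fell and none rose (list adjusted p = 0.0794), while 6 fell with arrays centred on the median of the genes and 4 with the shift by the median deviation. Of 10 Calvin cycle and photorespiration genes GDCSH fell by 0.48 and GLO3 rose by 0.81 (list adjusted p = 0.334). After centring on the median of the genes 4 of these and 1 antenna gene fell. Of 15 chlorophyll synthesis genes 3 rose, PORA (1.05), CPX (0.48) and PPOX1 (0.35), and the list had an adjusted p of 0.469. Of 6 genes of chlorophyll breakdown and senescence, OsRCCR1 (0.72), OsNOL (0.47) and OSL2 (0.44) rose and SAG12 fell by 0.29 (list adjusted p = 0.802). None of 5 carotenoid genes matched by name passed by limma over all genes. Adjusted over the list alone 2 fell. There were 3 with an unadjusted p under 0.05, and the list adjusted p was 0.334. In that list 3 fell with arrays centred on the median of the genes or shifted by the median deviation, 3 fell and 1 rose with an intensity trend, 1 fell with array weights and 2 fell in the brighter part of the probe sets. Of 7 photoprotection genes VTE1 (0.33) and VTE2-1 (0.39), of tocopherol synthesis, rose and the alternative oxidase AOX1a fell by 0.60 (list adjusted p = 0.338). Of 17 chloroplast proteases and chaperones 4 rose, led by FTSH6 (0.63), or 5 adjusted over the list alone, with an adjusted p of 0.890. Without mutant replicate 1 there were 2, and without mutant replicate 3, wild type replicate 2 or wild type replicate 3 there was 1.

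Genes that remove reactive oxygen went both ways, with 5 of 22 up and 2 down, or 6 and 2 adjusted over the list alone (list adjusted p = 0.802). The catalase catA rose by 1.45 (SE 0.07, adjusted p = 3.35e-05) and the superoxide dismutases SodCc2 and sodCp by 0.69 and 0.62, while the peroxiredoxin PRXIIE-2 fell by 0.83. Of 6 glutathione S-transferases matched by name GSTF1 and GSTZ5 fell. In the family of 25 fixed lists their adjusted p was 0.0595, and in that of 34 lists 0.0405, or 0.710 with an estimated correlation. Thioredoxins and glutaredoxins, an added list, were called lower in the 34 lists (adjusted p = 0.0336, or 0.710 with an estimated correlation), with 6 of 39 up and 8 down, or 6 and 9 adjusted over the list alone. With arrays centred on the median of the genes 5 rose and 21 fell, and with the shift by the median deviation 5 and 13. The falls numbered 5 without mutant replicate 2, 4 without mutant replicate 1 or 3, and 3 without any 1 of the wild type arrays. OsTrx14 (0.65), OsNrx1-1 (0.81) and OsNrx2 (0.72) rose, and GRXC15 and GRXC1 (-0.75) fell. The call was lost without mutant replicate 2 (adjusted p = 0.0694) and with arrays centred on the median of the genes (adjusted p = 0.0550). Over the 16 alternatives with the preset correlation the camera adjusted p ran from 0.00885 to 0.0694. That of the glutathione S-transferases ran from 0.0357 to 0.105 over the same alternatives. Of 44 heat-shock proteins and factors 9 rose, led by HSP17.9A (1.54), and 5 fell, led by HSP22.3 (-0.84), or 12 up and 8 down adjusted over the list alone, with a list adjusted p of 0.782. Without wild type replicate 2 or wild type replicate 3 there were 3 falls. By fry the reactive oxygen (adjusted p = 0.0227) and heat-shock lists (0.0302) were higher and the glutathione S-transferases lower (0.0493, or 0.0587 among all 34 lists), while the thioredoxins and glutaredoxins did not pass (0.266).

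Defence and hormone lists were mixed. Of 14 pathogenesis-related genes, Cht4, Cht5 and Cht7 (0.58) rose and Cht2 (-0.66) and Cht10 (-0.30) fell (list adjusted p = 0.802). Of 17 diterpenoid phytoalexin genes CYP76M7 (1.23) and CYP71Z6 (0.45) were among 3 that rose, and OsKSL10 and CYP99A2 (-0.31) fell, with 3 up and 3 down adjusted over the list alone (list adjusted p = 0.334). Phenylpropanoid genes rose in 10 of 20 cases and fell in 4, with an adjusted p of 0.736 for the list, while 6 rose and 6 fell with arrays centred on the median of the genes and 6 rose without wild type replicate 1. The lyase PAL (0.95), ROMT-17 (1.09) and OsCAD8C (0.77) rose, while the chalcone synthase OsCHS1 and the chalcone isomerase CHI, of the flavonoid branch, fell by 0.51 and 0.55. Of 35 jasmonate genes 4 rose, led by LOX1.1 (1.28), and 7 fell, among them OsTIFY11b (-0.72) and OsTIFY9 (-0.74) of the family of jasmonate response repressors (list adjusted p = 0.0794), while 2 rose and 12 fell with arrays centred on the median of the genes and 2 rose without wild type replicate 2. Of 6 WRKY factors matched by name WRKY9 (0.32) rose and WRKY24 (-0.74) fell (list adjusted p = 0.469). By fry the pathogenesis-related (adjusted p = 0.00659) and phenylpropanoid lists (0.0182) were higher. The pathogenesis-related list had a median change of -0.04 and a mean of 0.61, with Cht4 at 5.84 and Cht5 at 2.90.

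By camera no sugar, nitrogen or housekeeping list passed, while fry called the starch and sucrose list higher (adjusted p = 0.0493, or 0.0587 among all 34 lists). Of 49 starch and sucrose genes 10 rose and 2 fell, or 8 and 1 adjusted over the list alone. Over all genes 3752 of 17905 rose, a share near that of this list, whose median change was -0.04. With arrays centred on the median of the genes 8 of the list rose and 15 fell, and 6 rose without wild type replicate 2. The sugar exporter OsSWEET11 rose by 1.76 and the sucrose synthase OsSUS1 by 1.20 (list adjusted p = 0.338). Of the 17 nitrogen genes matched by name AMT2-1 (0.71) rose and NRT2.2 (-0.55), NIA1 (-0.36) and GLN1-2 (-0.27) fell (list adjusted p = 0.187). GLT2, which rose by 2.79, was not matched by the names used for this list, and the counts above leave it out. Its absence therefore does not say that it lies outside nitrogen assimilation. Of 9 clock and flowering time genes GI (0.44), OsPCL1 (0.51) and OsHd1 (0.66) rose and Hd3a fell (list adjusted p = 0.802). Cytosolic ribosomal proteins had 2 members up and 1 down of 23, or 1 and 1 adjusted over the list alone (list adjusted p = 0.552), and none of 15 proteasome subunits passed by limma, with 1 at an unadjusted p under 0.05 (list adjusted p = 0.327). For all other fixed lists the counts adjusted over the list alone equalled those over all genes.

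In 12 of the 34 lists the median, the mean and the camera direction differed in sign, while camera compares a list with all other genes, whose median lay above 0. These were the Calvin cycle, reactive oxygen, heat-shock, pathogenesis-related, diterpenoid, starch and sucrose, cytosolic ribosomal, vascular, endoplasmic reticulum folding, calcium, aquaporin and metallothionein lists. Of 23 lists with more rises than falls, 7 had more falls than rises with the shift by the median deviation, the heat-shock, pathogenesis-related, diterpenoid, cytosolic ribosomal, iron and zinc, calcium and metallothionein lists. With cyclic loess 1 turned, the iron and zinc list. With arrays centred on the median of the genes, which leaves the median of all genes at -0.12, 16 turned, and the chlorophyll synthesis and phenylpropanoid lists had as many rises as falls. The 16 were the chlorophyll breakdown, photoprotection, reactive oxygen, chloroplast protease, heat-shock, pathogenesis-related, diterpenoid, starch and sucrose, cytosolic ribosomal, clock, vascular, epidermis, iron and zinc, endoplasmic reticulum folding, calcium and metallothionein lists. Since both shifts lower all mutant values against wild type, turns toward falls follow from their construction. Counts of members under 4 moved by at most 2 when 1 array was left out.

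**Figure D2:**
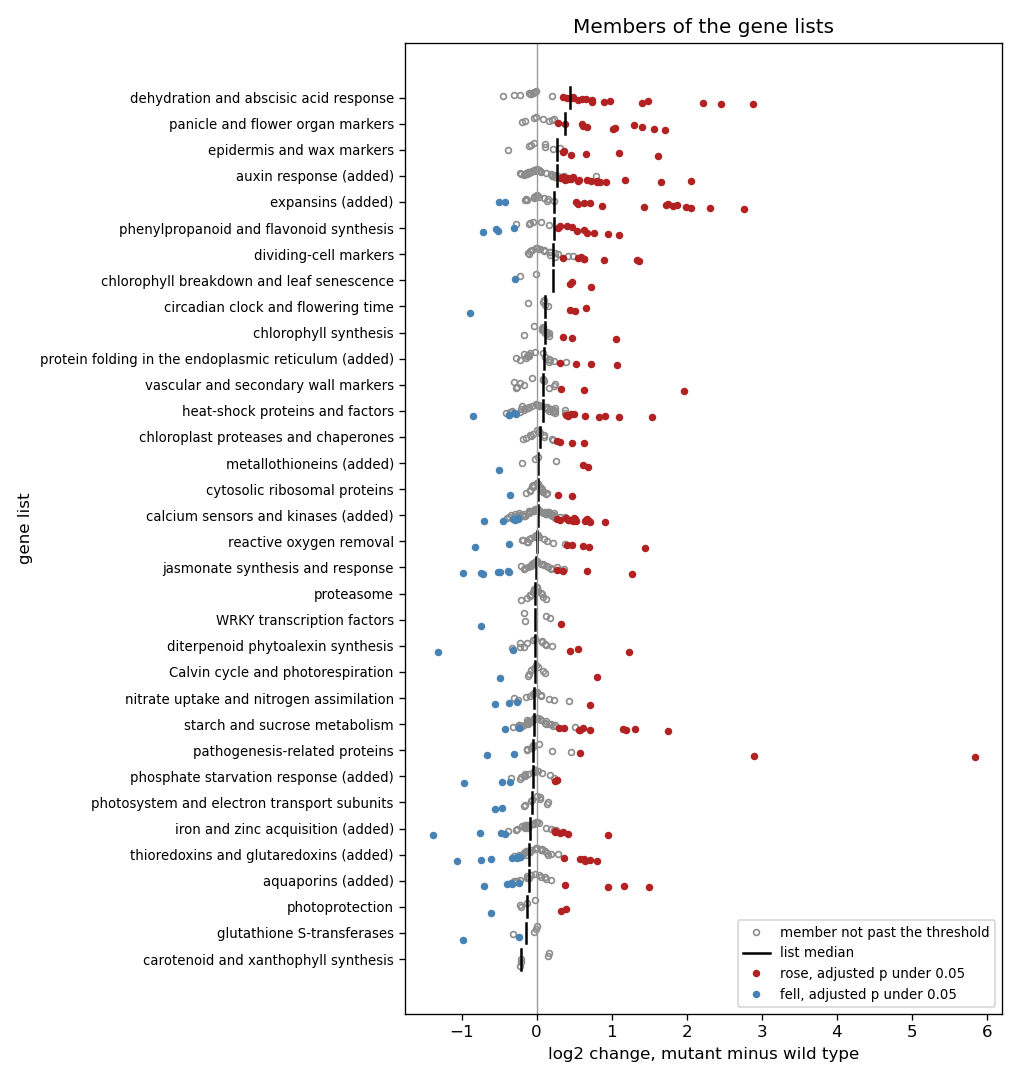
Log2 change, mutant minus wild type (x axis), of each member of the 34 gene lists tested (y axis, ordered by median). Filled points passed the limma threshold over all genes, open points did not, and black bars are list medians. The dehydration and abscisic acid list has the highest median, at 0.45.

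Of 64 reporter probe sets on the array, picked out by their identifiers after their values were seen, 3 rose and 1 fell. The largest change was that of RPTR-Os-U43284-1_s_at, which rose by 1.94 (SE 0.14, adjusted p = 0.000120), from 3.13 ± 0.18 in wild type to 5.07 ± 0.23 in mutant leaves (SD, n = 3 each). The sequences behind these probe sets, and whether any lies on the inserted T-DNA, are not given in the sources used here, so this rise does not check the labels. The targeted gene itself, Os01g0385400, was not analysed here, since the tables used here tie no probe set to it.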

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

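Centring on, or shifting by, the median of the genes and the family of all 34 lists were chosen after the data were seen. So was the choice of the 25 fixed lists as the main family, behind the count of 1 of 25. The other alternatives were fixed before. Of 125 named genes past the threshold, 111 had a value under each of the 16 alternatives run on genes, and 80 of these kept their call. The other 14 were removed by a filter in at least 1 alternative, and 12 of them kept their call where run. In all, 33 lost the call under at least 1 alternative and 0 changed direction where run. Of the 24 largest changes, 22 kept their call under all 16; OsKSL10, left out of the brighter probe sets, and LEA19, left out without _x_at and _s_at probe sets, kept it under the other 15. A change of 1 or more on the log2 scale left 899 probe sets and 593 genes, an adjusted p under 0.01 left 1980 and 2121, and a Welch test 229 and 1202. Leaving out 1 array gave 2319 to 5342 probe sets and 2700 to 4623 genes, with fewer samples in the fit. The count of lists past the threshold, 1 of 25, was 0 with the replicate block, array weights, an estimated correlation or without _x_at and _s_at probe sets; with an estimated correlation 0 lists had an unadjusted p under 0.05. It was 2 with each array centred on its median, cyclic loess, or centring or shifting by the median of the genes, and 4 with an intensity trend, in the brighter probe sets or with the mean of probe sets. It was 14 with fry, 7 in the family of all 34 lists, and 0 to 2 without 1 array. The cause was not tested. Over the 16 alternatives with the preset correlation the camera adjusted p of the dehydration list ran from 0.00109 to 0.104 and that of the panicle markers from 0.00158 to 0.120. With an estimated correlation it was 0.717 for both. The replicate block gave 5780 probe sets and 4754 genes. Deviations of same-numbered arrays correlated at 0.154, 0.00628 and 0.112, and those of differently numbered arrays at -0.277 to 0.228. The labels do not say whether the numbers pair the samples, and with 3 arrays per group these values cannot settle it. Values near the lower end of the scale lie close to background and understate changes. The targeted gene and lists from product names alone were not run, since the tables used here name neither.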

Other observations

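Chosen after the results were seen were the tests of a constant offset, of mutant replicate 1 for the excess of rises and of panicle tissue, and the count of splits for probe sets. Large changes also lay in genes without a name in the tables, singled out here after their values were seen. LOC4335526 rose by 5.14 on the log2 scale and LOC4325424 by 4.53, while LOC4347709 fell by 3.45 and LOC4347708 by 2.77. The adjusted p of these genes ran from 1.75e-06 for LOC4335526 to 1.12e-05 for LOC4347708.

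Of 32 iron and zinc genes 6 rose, among them OsIRT1 (0.95) and YSL13 (0.42), and 4 fell, OsNAS3 and YSL16 (-0.43) among them, with an adjusted p of 0.0687 in the 34 lists. With arrays centred on the median of the genes 1 rose and 12 fell, and with the shift by the median deviation 2 and 6. The rises numbered 3 without mutant replicate 1, mutant replicate 2 or wild type replicate 1 and 2 without wild type replicate 2 or 3, and the falls 2 without mutant replicate 3 or any 1 of the wild type arrays. Phosphate starvation genes were called lower (adjusted p = 0.0464, or 0.710 with an estimated correlation), with OsPHO1;3, OsSPX1 (-0.46) and OsSPX2 (-0.36) down and 2 of 21 up, or 2 down and 0 up adjusted over the list alone. The call was lost under 8 of 16 alternatives, cyclic loess (adjusted p = 0.0710) among them, and its adjusted p was 0.0676 without mutant replicate 1, 0.0694 without mutant replicate 2 and 0.0903 without wild type replicate 3, in a range of 0.0198 to 0.127, and by fry it was not made (0.0635). Of 23 aquaporins 4 rose, OsPIP2;6 (1.49), OsNIP1;1 (1.16) and OsTIP4;1 (0.95) among them, and 5 fell, with OsPIP2;4 at -0.70 (list adjusted p = 0.121). With arrays centred on the median of the genes 3 rose and 10 fell, and with the shift 4 and 9. The falls numbered 3 without mutant replicate 2 or wild type replicate 1, and 1 without mutant replicate 3, wild type replicate 2 or wild type replicate 3. Of 74 calcium sensors and kinases 15 rose and 7 fell, or 15 and 8 adjusted over the list alone (list adjusted p = 0.299), with CML15 at 0.91 and CML27 at -0.70. There 9 rose without mutant replicate 1 or wild type replicate 1 and 7 without wild type replicate 3, and the falls numbered 2 without mutant replicate 3 or wild type replicate 3 and 3 without wild type replicate 2. Protein folding genes of the endoplasmic reticulum had 4 of 20 up, 1 adjusted over the list alone, 1 without mutant replicate 1 or wild type replicate 3, and 2 without mutant replicate 3, wild type replicate 1 or wild type replicate 2 (list adjusted p = 0.863). Of 7 metallothioneins 2 rose, OsMT-I-2c by 0.69 among them, and 1, OsMT-I-2b, fell by 0.50 (list adjusted p = 0.776).

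Rises made up 76.8% of the genes past the threshold. Mutant replicate 1 argues little for this, since the share was 72.0% without it. With each array centred on its median over probe sets the share was 86.2%. After cyclic loess, the test fixed beforehand for an array-wide or intensity-dependent trend, the share was 69.1%, above the bound set for that explanation. That bound was too narrow, because loess runs over all probe sets and leaves an offset of the annotated genes in place: after each array was shifted by the median deviation of its genes the share was 55.5%. By mean level, the median change was 0.053 in dim, 0.180 in middle and 0.055 in bright genes, so the difference was not the same at all levels. The shift centres the genes by construction. An offset between arrays, a difference that varies with level and a true excess of rises in the mutant may each give this pattern and cannot be told apart.

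The rise of the dehydration and abscisic acid genes was weighed against the same explanations. Against 16 rising members, 14 rose without mutant replicate 1, 15 after cyclic loess, 14 with the shift by the median deviation and 12 with arrays centred on the median of the genes, which argues against that array and against an array-wide or intensity-dependent trend. A different water status of the mutant plants at sampling, or an effect of the insertion, may lie behind the pattern, and neither was tested, since the labels give neither water status nor a second insertion line.

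The rise of panicle and flower organ markers was not removed by cyclic loess, after which 10 of 19 members rose, or by the shift and the centring on the median of the genes, after each of which 9 rose. Panicle tissue carried into the mutant samples could raise them. The 12 floral MADS members had a median change of 0.65 and the 7 anther members 0.0822, of which OsC4 and CYP703A3 rose, while MADS34, a MADS-box gene outside the list, fell by 1.26. The anther members ranged from -0.19 to 1.30, so their median does not decide between tissue carried over and expression in the mutant leaf. The highest wild type level of a member was 8.23, and 0 members belonged to another list. The median of the members' mean levels over all arrays was 4.33, below the median of each array, so most members were dim.

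The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 5632 probe sets, and 1 of the 10 splits, the real one, gave as many. The highest of the others was 0, with the corresponding gene counts 4883 and 0. Each other split mixes mutant and wild type arrays in both groups, so the difference between them adds to the spread within groups. The 0 calls therefore do not decide whether the real grouping arose by chance. For gene lists the real split gave 1 list and the highest of the others 3, and 4 of the 10 splits gave at least 1.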
